A study of Mus musculus and Homo sapiens with 14 samples.

How the data were processed

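RNA-seq was analysed from 14 libraries. The mouse part held 8 libraries of osteoblastic lineage cells (OBCs) sorted from the femurs of KaLwRij mice, a C57BL substrain, 4 from mice given an LNA-modified antisense oligonucleotide against miR-138 (anti-miR-138) and 4 from mice given a scramble oligonucleotide. Per the labels' protocols, the sort took lineage-negative cells without CD45, CD31 and Sca-1 and with CD51, into the lysis buffer of the SMART-Seq v4 ultra low input kit, and libraries were made with Nextera XT. The human part held 6 libraries of bone marrow mesenchymal stromal cells (MSCs) grown together with OPM2, an established human myeloma cell line, 3 treated with anti-miR-138 and 3 with scramble. Per the labels' protocols, TRIzol was used to extract RNA of MSCs from co-cultures, and the NEBNext Ultra kit for libraries is named for OPM2 cells alone. Whether the human RNA came from both cell types or from separated MSCs is therefore unclear, and so are the cells to which the human values belong. Groups came from the treatment label of each library. The mouse replicate numbers are those of the library titles (1, 3, 4 and 6 treated, 1 to 4 scramble), and the human replicates were numbered 1 to 3.

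The authors deposited 1 RSEM gene table per library, and the expected counts of those tables were used, per the file headers. Expected counts are estimated counts in which reads that match several genes are divided among them by a model, so counts of near-identical genes (the mitochondrially encoded genes and their nuclear copies, the alpha globin pair) are uncertain. Reads of overlapping or antisense genes are uncertain too, since the sources used here give no strand setting. Per the submitters' processing notes, Picard, STAR, RSEM and DESeq2 were used with the builds mm10 and GRCh37, with no versions and no role stated. The annotation release and filters are not given in the sources used here. There were 47643 genes per mouse library and 57820 per human library.

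Gene symbols were taken from GENCODE M21 on GRCm38, the build mm10 names, by identifier without its version, and 47224 mouse identifiers (99.1%) had one. The human tables do not pair their identifiers with names, and no table with human names was used here. Human gene lists, human miR-138 sites and the comparisons of mouse with human genes were therefore left out, and at most 2 human identifiers that rose and 2 that fell are given.

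Expected counts were rounded to whole numbers. Each part was tested alone with edgeR 4.0.16 in R 4.3.3: low counts were removed with filterByExpr, libraries were scaled with TMM, and a robust quasi-likelihood fit was tested two-sided with Benjamini-Hochberg adjustment at 0.05. Every adjusted p of a gene is from that test unless another tool is named. The SE of an edgeR log2 fold change was derived as its absolute value divided by the square root of the test's F statistic. CPM are counts relative to the TMM-scaled library size, and log2 CPM carry a prior count of 2. Means are given with the SD over libraries. Alternatives were RLE scaling, library totals alone, DESeq2 1.42.0, limma-voom 3.58.1 with sample quality weights, no filter, a filter of CPM of at least 1 in at least 4 (mouse) or 3 (human) libraries, each library left out in turn, and a block. These choices, the gene lists and the rule for named genes were fixed before the data were examined. The fits without the scramble libraries 1 and 3, the list tests with library totals alone and the permutation of list means were chosen afterwards.

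The 32 mouse gene lists were tested with camera on voom values with a preset inter-gene correlation of 0.01, adjusted over the lists, and again with the correlation estimated per list. As a test that rests on the libraries alone, the mean log2 CPM of each list per library was compared between groups by exact permutation over the 70 labelings of 4 and 4, two-sided, for which the smallest p is 0.0286. The lists were osteoblast commitment, bone matrix and mineralization, osteocyte, BMP, Wnt and TGF-beta signalling, fibrillar and interstitial matrix, literature miR-138 targets, marrow stromal niche factors, osteoclast regulators, osteoclast, adipocyte, chondrocyte, endothelial, myeloid and leukocyte, erythroid, B lineage and plasma cell, megakaryocyte and platelet, pericyte and smooth muscle, skeletal muscle, cell cycle, interferon response, NF-kB and inflammatory cytokines, hypoxia and glycolysis, oxidative phosphorylation, immediate early and dissociation stress, unfolded protein response, p53 targets, cholesterol synthesis, ribosomal proteins and mitochondrially encoded genes, and 1 further list that is not reported here.

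Sites for miR-138-5p (AGCUGGUGUUGUGAAUCAGGCCG) were searched in the longest annotated 3′ UTR of each of 21037 mouse genes, as the complement of nucleotides 2 to 8 (CACCAGC) and the 8mer form with a following A (CACCAGCA). There were 2501 genes with a site, 898 of them with an 8mer. Genes with a site were compared with the other genes with a 3′ UTR by camera and by the difference between group means of log2 CPM per gene. Medians of that difference were compared over all these genes and within 25 strata (5 of UTR length by 5 of mean expression), with exact permutation p values over the same 70 labelings.

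Named genes were up to 12 per direction that passed the adjusted threshold, had an average log2 CPM of at least 1 and had treated and control libraries that did not overlap, by size of change. Where fewer passed, the places were filled by smallest p under the same criteria, as values that did not pass. To these came up to 4 members of each list past the threshold or otherwise the 2 with the smallest p, and a fixed set: the genes of miR-138, bone genes, reported miR-138 targets and genes of the sort gate. Predicted models, pseudogenes and, among human genes, sex-linked, HLA and commonly deleted genes were not named. Known sex-linked identifiers were also kept out of the human gene table.

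No pair of libraries within a group agreed within sampling noise: the chi-square of their counts per degree of freedom was 59.1 or more. The human titles run in neighbouring numbers, 1 scramble and 1 treated library each. No label says that these neighbours share a donor. Their deviations from the group means were correlated across genes at 0.58, 0.73 and 0.76, against -0.22 to -0.55 for the other combinations of a treated and a control library. By the criterion set beforehand, every pair over 0.1, the human libraries were taken as paired, and the fit with the pair as a block is given beside the main one. Nothing else in the labels ties a human library to a donor, and p-values of the main fit measure the spread between these libraries.

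The gene test was tested on simulated data with the means, library sizes and gene-wise spread of each part and 200 changed genes, 50 per fold size. In the mouse simulation, on 12667 genes, 0 of 50 genes changed 2-fold, 0 of 50 changed 4-fold, 8 of 50 changed 8-fold and 16 of 50 changed 16-fold were recovered. In the human simulation, on 17626 genes, the numbers were 20, 38, 49 and 48 of 50, with 18 unchanged genes called. With the spread within the human pairs and the block, on 17653 genes, 50 of 50 were recovered at each size and 28 unchanged genes were called. The list test, camera with the preset correlation, on 13328 genes, called the ribosomal protein list in 20 of 20 runs and the genes with a site in 20 of 20 runs when these were shifted by 0.5 on the log2 scale, and in 0 of 20 when shifted by 0.1 or not at all. The simulated genes were drawn independently, whereas the estimated correlation of the real ribosomal protein list was 0.79. These runs therefore do not show how often camera calls a list of correlated genes by chance. The shift of 0.5 was added after the one of 0.1 had not been recovered. At least 1 of the other lists was called in 1 of 20 runs with no shift, in 1 of 20 with the shift of 0.1 and in 5 of 20 with the shift of 0.5. Some of those lists hold genes with a site, which were shifted too, so only the runs with no shift count false calls.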

Results

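The libraries addressed how inhibition of miR-138, a microRNA studied as a brake on bone formation in the myeloma marrow niche, acts on the transcriptome of bone-forming cells. The mouse OBC libraries held 18666975 to 31988369 expected counts in the anti-miR-138 group and 34504687 to 40106732 in the scramble group, and 17499 to 22788 against 15195 to 18927 genes had a count. Every treated mouse library thus held fewer counts than every scramble library, so depth and treatment cannot be told apart in mouse. The human co-culture libraries held 43943040 to 46682002 with anti-miR-138 and 38845678 to 47564158 with scramble. Mouse replicates differed far more from each other than human ones. Spearman's correlations across genes between replicates of a group were 0.59 to 0.84 in mouse and 0.97 to 0.98 in human, and the biological coefficient of variation was 1.17 against 0.31.

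In OBCs of treated mice, no gene passed the threshold of edgeR's test. Among the named genes, treated OBCs held more of the transcription factor gene Trps1 (207 ± 102 CPM against 42.4 ± 27, SD, n = 4), of the integrin gene Itgav (93.1 ± 18.7 against 43 ± 10.6) and of the Hippo pathway coactivator gene Wwtr1 (195 ± 42.2 against 92 ± 14.5). They held less of the integrin gene Itgb2 (10 ± 5.27 against 180 ± 160) and the gelatinase gene Mmp9 (17.8 ± 8.47 against 396 ± 405), both abundant in leukocytes. In each of these 5 genes the treated and control libraries did not overlap, as held for 5.57% of all tested genes. Itgb2 and Mmp9 were chosen by that criterion. Trps1 and Itgav came from the fixed set, in which other genes, such as Runx2 and Ptk2, overlapped. Wwtr1 was taken from the osteoblast commitment list as its member with the smallest p, a choice that favours libraries that do not overlap. edgeR's test gave 0 of 13328 genes at an adjusted p of 0.05, with 743 at an unadjusted p under 0.05 (304 of them higher) and a smallest adjusted p of 0.621. DESeq2 called 435 genes, 355 higher and 80 lower, among them Itgb2 (DESeq2 adjusted p = 0.00257) and Mmp9 (0.00408) but not Trps1 (0.114), Itgav (0.392) or Wwtr1 (0.286), and limma-voom with sample weights called 0. With DESeq2, 6 other splits of the 8 libraries drawn at random gave 139 to 689 genes. Of those 435 genes, 148 were among the genes that edgeR tested and 194 had treated and control libraries that overlapped. Without the scramble libraries 1 and 3, which stood apart with 12.6% and 8.5% of tested genes at 0 counts against 1.8% to 4% in the other libraries, edgeR's count was 0 of 16313.

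The genes of miR-138 itself, Mir138-1 (chromosome 9, 122682876 to 122682974, GRCm38) and Mir138-2 (chromosome 8, 94324311 to 94324381), had 0 counts in all 8 mouse libraries. This does not check the labels, because the inhibitor binds the mature microRNA, which a messenger RNA library does not measure. Of the genes reported in the literature as miR-138 targets, Trps1 (chromosome 15, 50654752 to 50890463, minus strand) was 4.88-fold higher in treated OBCs, with a log2 fold change of 2.29 ± 0.58 (SE), and it did not pass the threshold (adjusted p = 0.877). Its 3′ UTR of 5923 bases holds an 8mer site, CACCAGCA, at 50655467 to 50655474, 5201 bases after the stop codon, in the context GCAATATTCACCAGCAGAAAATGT. Ptk2, which encodes focal adhesion kinase, has an 8mer site at 73205985 to 73205992 on chromosome 15, 56 bases after the stop codon of a 946-base UTR. Its level was 34.9 ± 6.32 CPM in treated and 30.5 ± 39.6 in control OBCs (log2 fold change 0.19 ± 1.2, SE). Rock2, with an 8mer site at 16984971 to 16984978 on chromosome 12, had 105 ± 78.4 against 104 ± 39.8 CPM. Sulf1, a heparan sulfatase gene with a 7mer site (CACCAGC) at 12858864 to 12858870 on chromosome 1, had 21.1 ± 21.7 against 18.2 ± 21.7 CPM. Lcn2, the neutrophil lipocalin gene, also on that list and with a 7mer site, lay the other way at 66.5 ± 90.7 against 1396 ± 1995 CPM. DESeq2 called Lcn2 (DESeq2 adjusted p = 0.0339) and edgeR did not (0.877). Its control mean rested largely on scramble replicate 3 (4381 CPM, against 202 to 531 in the other scramble libraries). The 26 literature targets as a list did not differ from other genes (camera, adjusted p = 0.981), with 15 members above and 11 below 0. Its mean per library was 5.12 ± 0.14 log2 CPM in treated and 4.81 ± 0.23 in control OBCs (exact permutation p = 0.0571, 0.457 adjusted over the lists), a difference in the opposite direction to that of camera.

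Across the transcriptome, genes with a miR-138 site did not differ detectably from the others. The change was taken here as the difference between group means of log2 CPM. This is not edgeR's log2 fold change, whose median over all mouse genes was -0.1. The 1713 tested genes with a 7mer or 8mer site had a median change of 0.25 and the 10034 genes without one 0.15, a difference of 0.1 (exact permutation p = 0.114). After matching on UTR length and expression the difference had the opposite sign, -0.063 (exact permutation p = 0.314). Beside these exact permutation tests, camera put the genes with a site higher with p = 0.423, and 0.407 with an estimated correlation. For the 612 genes with an 8mer the difference was 0.067 before and -0.043 after matching (exact permutation p = 0.343 and 0.686). On simulated data with genes drawn independently, camera found a shift of 0.5 in 20 of 20 runs and one of 0.1 in 0 of 20. A shift of that smaller size was thus not detectable by camera at this spread, and the permutation tests were not simulated.

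Bone matrix genes were among the most abundant in OBCs, and none passed the threshold between treatments. Sparc, which encodes osteonectin, stood at 33806 ± 7071 CPM in treated and 30957 ± 7650 in control libraries. Col1a1, the collagen type I gene, stood at 5582 ± 3152 against 11715 ± 8702 CPM. Osteopontin (Spp1) stood at 15241 ± 6908 against 34293 ± 28021, bone sialoprotein (Ibsp) at 5350 ± 2042 against 7807 ± 3821 and osteocalcin (Bglap) at 2261 ± 1987 against 4914 ± 4583. The osteoblast transcription factor gene Runx2 had 76.7 ± 21.1 against 92.5 ± 39.9 CPM, Sp7 (osterix) 35.9 ± 8.66 against 102 ± 110, and the alkaline phosphatase gene Alpl 736 ± 237 against 1049 ± 543. The adjusted p values were high (0.901 for Col1a1 and Sp7, 0.976 for Runx2 and 0.939 for Alpl). The osteocyte gene Sost, which encodes sclerostin, had 0 counts in 6 libraries and 1 in the other two. The lists of osteoblast commitment (adjusted p = 0.884), bone matrix and mineralization (0.981) and osteocyte genes (0.332) did not pass camera. Within them, Wwtr1 passed when adjusted over the list alone (1 of 12 osteoblast commitment genes), and 0 of 24 bone matrix genes did. The direction of the bone matrix list depended on the libraries: it passed camera in the higher direction without the scramble libraries 1 and 3 (adjusted p = 0.0129) and in the lower direction without scramble replicate 4 (0.0262). With an estimated correlation and all libraries its adjusted p was 0.989. The list median and the mean per library lay on opposite sides for osteoblast commitment (median log2 fold change -0.13, mean difference 0.25) and bone matrix (-0.31 and 0.03). The bone matrix members with the smallest p lay higher in treated OBCs: Omd, the osteomodulin gene, at 354 ± 310 against 72.8 ± 55.2 CPM, and Plod2, a collagen lysyl hydroxylase gene, at 729 ± 119 against 401 ± 105. Dmp1, a matrix gene of osteocytes, lay lower at 418 ± 281 against 1571 ± 1509 CPM with all libraries. Without the scramble libraries 1 and 3 the Dmp1 log2 fold change was 0.21 in place of -1.91, the Spp1 log2 fold change 0.36 in place of -1.17 and the Alpl log2 fold change 0.05 in place of -0.51.

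**Figure D1:**
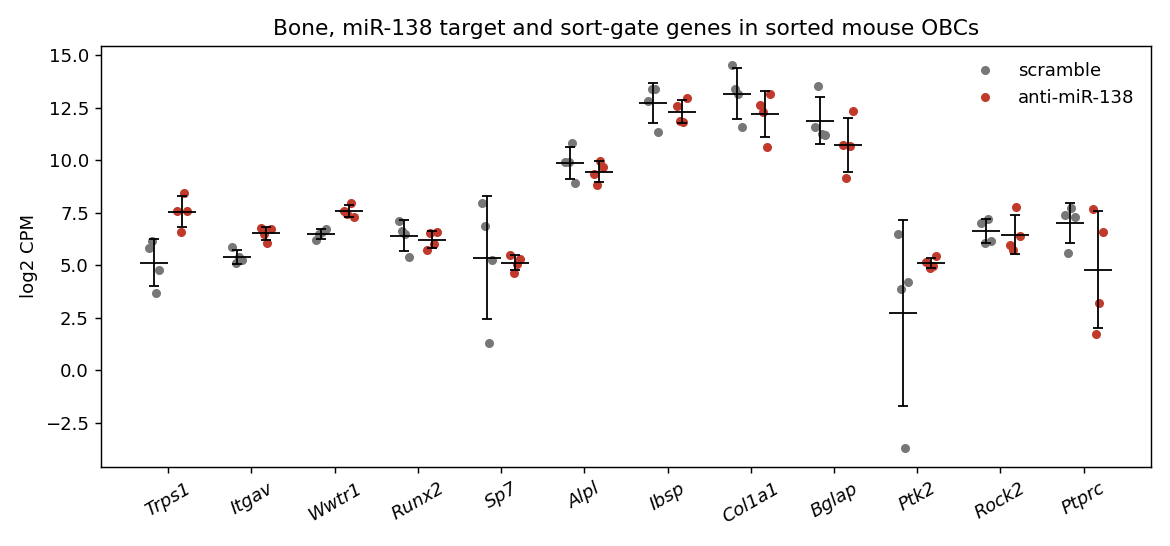
Log2 CPM (y axis, here without a prior count) of 12 genes in the mouse OBC libraries, with 1 point per library (4 scramble in grey, 4 anti-miR-138 in red), and the mean with the SD as whiskers. The treated libraries lie above all scramble libraries for Trps1, Itgav and Wwtr1, and the groups overlap for the other genes.

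Among other genes higher in treated OBCs were Pam, a peptide amidating enzyme gene (130 ± 45.7 against 30.4 ± 10.4 CPM), Htra3, a secreted protease gene (232 ± 38.3 against 95.2 ± 25), Unc5c, a netrin receptor gene (155 ± 98.5 against 35.6 ± 14), and Usp33 (54.6 ± 25.6 against 5.12 ± 3.98). Others were present in treated and nearly absent from control libraries: the vitronectin gene Vtn (15.9 ± 10.3 against 0.032 ± 0.0332 CPM), Plxdc1 (20.4 ± 22.4 against 0.166 ± 0.129), and the integrin gene Itga8 (5.09 ± 1.93 against 0.0536 ± 0.0254). This also held for the mesenchymal transcription factor gene Tbx18 (15.4 ± 10.5 against 0.0799 ± 0.11), the urokinase gene Plau (5.41 ± 3.83 against 0.00982 ± 0.0196), Dnah7b (6.89 ± 5.82 against 0.00982 ± 0.0196), Fggy (11.1 ± 9.47 against 0.0302 ± 0.042) and Wdr78 (5.85 ± 3.83 against 0.0191 ± 0.0256). None of these 12 genes passed edgeR's test (adjusted p = 0.877 for each). DESeq2 called 10 of them, with adjusted p values from 1.69e-10 (Vtn) to 0.0485 (Pam), and did not call Htra3 (0.176) and Unc5c (0.0844). Of all tested genes, 743 had treated and control libraries that did not overlap, 5.57%, and 385 of them were higher. Chance gives 2.86% on average over the splits of the libraries. Genes vary together, so single splits can lie far from that average. The share was not computed for other splits, and whether 5.57% exceeds chance is therefore not known.

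Leukocyte genes lay lower in treated OBCs. Apart from Itgb2 and Mmp9, the genes with the smallest p on the lower side were the leukotriene receptor gene Ltb4r1 (0.0359 ± 0.0544 against 53 ± 53.8 CPM), Klhl6 (0.0216 ± 0.0431 against 39.6 ± 41), the B-cell linker gene Blnk (0.075 ± 0.087 against 29 ± 10.6), and the sialic acid receptor gene Cd33 (12.9 ± 7.99 against 110 ± 77.1). They also included the small GTPase gene Rac2 (70.7 ± 37.8 against 385 ± 241) and the formyl peptide receptor gene Fpr2 (7.63 ± 4.3 against 65.4 ± 61.1). Fam136a, Rhov, Ipcef1 and Sarnp completed that side, and edgeR's adjusted p was 0.621 for Ltb4r1 and Klhl6 and 0.877 for the rest. DESeq2 called 8 of these 12 genes, with adjusted p values from 2.37e-09 (Blnk) to 0.0309 (Fpr2). The myeloid and leukocyte list passed camera in the lower direction (adjusted p = 4.71e-08, 13 of 14 members below 0, median log2 fold change -2.76), and its adjusted p was 0.592 with an estimated correlation. Adjusted over the list alone, 6 of its 14 members passed, all lower, and 0 did over all genes. S100a9, a neutrophil calprotectin gene, had 644 ± 743 against 6615 ± 7735 CPM and the leukocyte coronin gene Coro1a 51.9 ± 46 against 320 ± 247. The list's mean per library was 3.14 to 6.79 log2 CPM in treated and 5.57 to 9.48 in control libraries, and its group difference of -2.98 had an exact permutation p of 0.0857 (0.457 adjusted over the lists). Genes of the sort gate were Ptprc (CD45, gated out) at 78.2 ± 94.5 against 147 ± 69.6 CPM, Pecam1 (CD31, gated out) at 0.684 ± 0.564 against 2.05 ± 3.62, Ly6a (Sca-1, gated out) at 96.3 ± 133 against 48.5 ± 51.4, and Itgav (CD51, gated in), given above.

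Cartilage genes lay higher in treated OBCs. The chondrocyte list passed camera (adjusted p = 2.07e-05, 13 of 14 members above 0, median log2 fold change 1.45), and its adjusted p was 0.686 with an estimated correlation. Sox6, a transcription factor gene of chondrocytes, had 66 ± 14.4 against 18.8 ± 12.6 CPM and the type IX collagen gene Col9a2 810 ± 491 against 256 ± 176. The list's mean was 6.68 to 9.93 log2 CPM in treated and 5.22 to 8.59 in control libraries (exact permutation p = 0.143 for a difference of 1.69). Without the scramble libraries 1 and 3 the difference was 0.51 (camera adjusted p = 0.00336). The cholesterol synthesis list also lay higher (adjusted p = 0.00269, 16 of 19 members above 0), with an adjusted p of 0.769 with an estimated correlation and 2.8e-05 to 0.0514 with 1 library left out, the highest without scramble replicate 2. This list had means of 2.8 to 5.37 log2 CPM in treated and 1.09 to 4.73 in control libraries (exact permutation p = 0.2 for a difference of 1.47). Its members with the smallest p were Fdft1, the squalene synthase gene (86.5 ± 35 against 42.8 ± 7.3 CPM), and Sc5d, a sterol desaturase gene (88.1 ± 32.2 against 18.4 ± 22.8).

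Genes of ribosomes and mitochondria lay lower in treated OBCs. All 75 ribosomal protein genes had a log2 fold change below 0 (median -0.65, camera adjusted p = 4.51e-26), as had 16 of 17 oxidative phosphorylation genes (median -0.59, adjusted p = 1.17e-05) and all 13 mitochondrially encoded genes (median -0.87, adjusted p = 0.000426). With an estimated correlation the adjusted p values were 0.686, 0.592 and 0.769. Rpl26 had 110 ± 14.7 against 198 ± 31.8 CPM, Rpl19 303 ± 33.8 against 524 ± 109, the cytochrome oxidase gene Cox4i1 277 ± 39.2 against 458 ± 46.6 and the complex I gene Ndufb8 113 ± 14.3 against 204 ± 74. The exact permutation p of the list means was 0.0857 for ribosomal proteins, 0.0571 for oxidative phosphorylation and 0.314 for mitochondrially encoded genes. Without the scramble libraries 1 and 3 the mitochondrially encoded list no longer differed (adjusted p = 0.904), and with 1 library left out its adjusted p was 1.43e-13 to 0.0724, the highest without scramble replicate 3. No list passed camera with an estimated correlation or the permutation of list means after adjustment, whereas 6 of 32 passed with the preset correlation, and 13 did without the scramble libraries 1 and 3. The smallest permutation p is 0.0286, so after adjustment over 32 lists the permutation could pass only with many lists at that p. Its lack of calls therefore decides little.

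**Figure D2:**
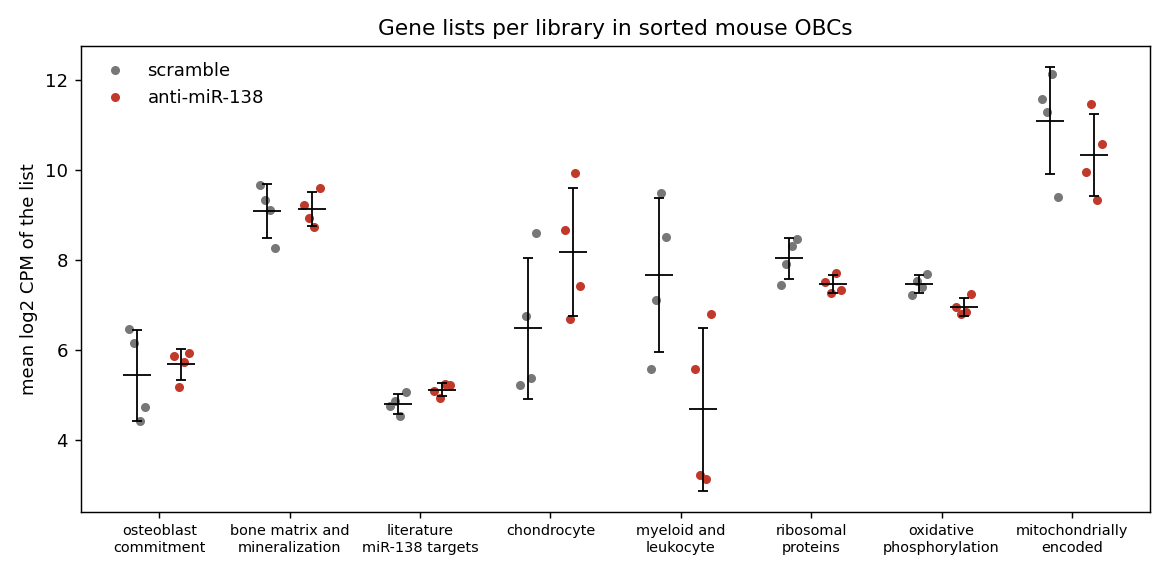
Mean log2 CPM of the genes of 8 lists (y axis) in each mouse OBC library, with 1 point per library (4 scramble in grey, 4 anti-miR-138 in red), and the mean with the SD as whiskers. Treated libraries lie lower on average for the leukocyte, ribosomal protein and mitochondrial lists and higher for the chondrocyte list, and at least 1 library overlaps the other group in every list shown.

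The other lists given here did not pass camera with all libraries. For signalling and matrix lists the adjusted p values were 0.0821 for TGF-beta, 0.428 for BMP, 0.485 for Wnt and 0.461 for fibrillar and interstitial matrix. The means per library of the TGF-beta list (5.38 to 5.83 against 4.67 to 5.16 log2 CPM) and of the BMP list (4.64 to 4.9 against 3.07 to 4.6) did not overlap between treated and control OBCs, with an exact permutation p of 0.0286 each, the smallest the design gives, and 0.457 adjusted over the lists. Camera called the TGF-beta list higher without anti-miR-138 replicate 4 (adjusted p = 0.0462), anti-miR-138 replicate 6 (0.0391) or scramble replicate 1 (0.00415), and without the scramble libraries 1 and 3 (0.000155). It called the BMP list higher without scramble replicate 1 (0.0344) and without the scramble libraries 1 and 3 (0.0297), and the fibrillar matrix list higher without the latter (0.00328). These calls depended on the libraries and on the correlation: without scramble replicate 4 the BMP (0.92) and fibrillar matrix (0.701) lists lay in the lower direction and the TGF-beta list in the higher one (0.701), and with an estimated correlation the adjusted p was 0.686 for TGF-beta, 0.827 for BMP and 0.836 for fibrillar matrix. Skil, a feedback regulator of TGF-beta signalling, had 243 ± 33.6 against 121 ± 37.3 CPM and the BMP ligand gene Bmp5 31.9 ± 29.4 against 1.56 ± 2.26, with 2 scramble libraries at 0 counts. Id3, the BMP list member with the next smallest p, lay lower at 992 ± 316 against 1894 ± 857 CPM. The collagen gene Col12a1 had 772 ± 441 against 193 ± 117, and the gelatinase gene Mmp2 229 ± 81.6 against 672 ± 411. For cells and factors of the marrow they were 0.485 for stromal niche factors and for osteoclast regulators, 0.939 for osteoclast, 0.927 for adipocyte, and 0.603 for endothelial genes. They were 0.387 for erythroid, 0.694 for B lineage and plasma cell, 0.485 for megakaryocyte and platelet, 0.651 for pericyte and smooth muscle and 0.428 for skeletal muscle genes. The erythroid and B lineage lists passed in the lower direction without scramble replicate 1 (0.0226 each) and without the scramble libraries 1 and 3 (0.0129 and 7.45e-05). Without scramble replicate 4 the erythroid list had an adjusted p of 0.857 and the B lineage list lay in the higher direction (0.719), and with an estimated correlation the values were 0.876 and 0.933. The osteoclast list was split: Mmp9 lay lower and Nfatc1, a transcription factor gene of osteoclasts, higher (282 ± 95.4 against 94.4 ± 45.4 CPM), and these 2 of its 4 tested genes passed when adjusted over the list alone. Csf1, a macrophage growth factor gene, had 13.8 ± 9.79 against 66.3 ± 62 CPM and Il6, an inflammatory cytokine gene, 680 ± 546 against 169 ± 97. For programs of growth and stress the adjusted p values were 0.332 for cell cycle, 0.345 for interferon response, 0.143 for NF-kB and inflammatory cytokines, 0.652 for hypoxia and glycolysis, 0.651 for immediate early and dissociation stress, 0.255 for unfolded protein response and 0.981 for p53 targets. Cell cycle passed in the higher direction without anti-miR-138 replicate 4 (0.0462) or scramble replicate 4 (0.0234), but lay in the lower direction without scramble replicate 1 (0.294), without the scramble libraries 1 and 3 (0.0592) and with the title number as a block (0.871). NF-kB passed in the higher direction without anti-miR-138 replicate 4 (0.0462). Hypoxia passed in the higher direction without scramble replicate 1 (0.0226) and without the scramble libraries 1 and 3 (0.00243), and lay in the lower direction without anti-miR-138 replicate 4 (0.704), scramble replicate 2 (0.733) or scramble replicate 4 (0.857). Immediate early genes passed in opposite directions, lower without scramble replicate 4 (0.0204) and higher without the scramble libraries 1 and 3 (0.00298). With an estimated correlation the adjusted p was 0.876 for cell cycle, 0.686 for NF-kB, and 0.933 for hypoxia and for immediate early genes. The hexokinase gene Hk2 had 160 ± 28.9 against 82.1 ± 24.1 CPM and the heat shock gene Dnajb1 899 ± 521 against 294 ± 135. Beside Hk2 on the hypoxia list, Ndrg1 lay lower (86.3 ± 30.9 against 200 ± 170 CPM). Beside Il6 on the NF-kB list, Cxcl2 lay lower (61.5 ± 67 against 484 ± 762 CPM).

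In the human co-cultures, most genes that passed the threshold in the fit without pairs were of low abundance and lower with anti-miR-138. The protocols leave unclear whether this RNA came from both cell types or from separated MSCs. edgeR's test gave 234 of 17990 genes past the threshold, 27 higher and 207 lower with anti-miR-138, with 2327 at an unadjusted p under 0.05. The genes called lower had a median mean level of 0.917 CPM and a median log2 fold change of -3.09, and 206 of the 207 differed at least 2-fold. The genes called higher had a median level of 33.6 CPM and a median log2 fold change of 1.06. In all 234, treated and control libraries did not overlap, which held for 20.2% of all tested genes. Chance gives 10% for libraries that are not paired, a share that does not hold for libraries taken as pairs. With the pairs as a block, 3530 genes passed, 1753 higher and 1777 lower, including all 234, so that the share of higher genes was 49.7% in place of 11.5%. The genes higher in that fit had a median level of 28.4 CPM and a median log2 fold change of 0.4, and those lower 2.99 CPM and -0.95. With 1 library left out, edgeR's fit without pairs called 0 or 1 genes, while DESeq2 with all libraries called 878 (218 higher). The same direction in all 3 pairs was found for 55.5% of tested genes, where chance gives 25% on average over treatment assignments. Genes vary together, and the share was not computed for the other assignments.

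Among the called human genes that met the rule for named genes, those with the largest changes are given here by identifier. Over all called genes the log2 fold change ran from -9.11 to 9.43. ENSG00000167995.11 rose from 14.8 ± 4.04 to 79.9 ± 22 CPM (n = 3; log2 fold change 2.44 ± 0.3, SE, adjusted p = 0.0295, and 1.57e-07 with the pairs as a block). ENSG00000157514.12 rose from 241 ± 24.6 to 727 ± 158 CPM (adjusted p = 0.0249, and 0.00391 with the block). ENSG00000101204.11 fell from 8.67 ± 3.56 to 0.046 ± 0.0614 CPM (adjusted p = 0.0246, and 6.48e-05 with the block) and ENSG00000235400.1 from 11.5 ± 4.47 to 0.0981 ± 0.0276 CPM (adjusted p = 0.014, and 4.8e-07 with the block). In the fit without pairs all 4 calls were lost with 1 library left out, except ENSG00000235400.1 without scramble replicate 1 (adjusted p = 0.0436, and up to 0.109 without another library). Human treated libraries also detected fewer genes than their paired controls, 25275 against 27215, 26066 against 27292 and 27751 against 29432 genes with a count.

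**Figure D3:**
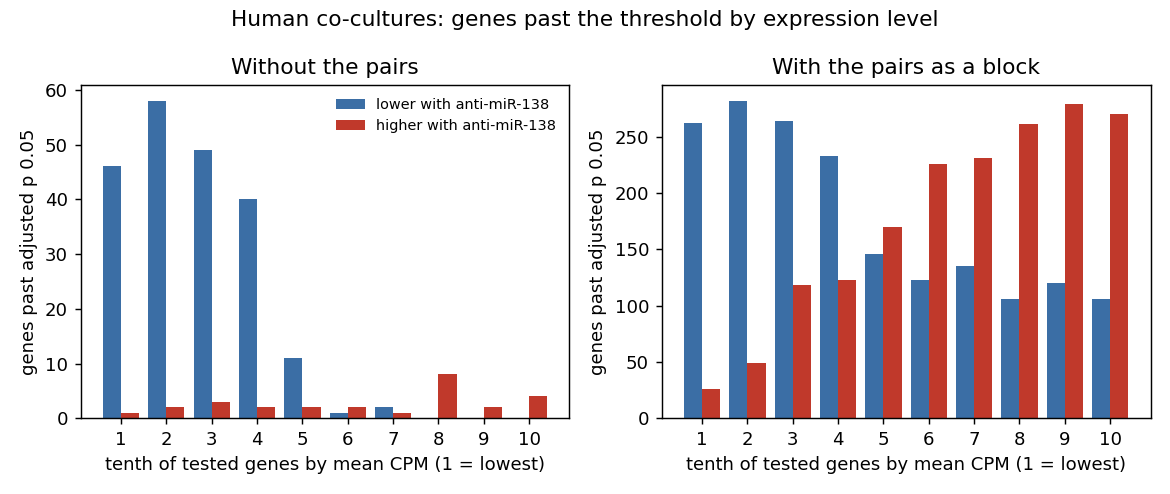
Number of genes past an adjusted p of 0.05 (y axis) in 10 equal bins of the tested human genes by mean CPM (x axis, 1 is the lowest), lower (blue) and higher (red) with anti-miR-138, in the fit without the pairs (left) and with the pairs as a block (right). Genes called lower lie mostly in the lowest 4 bins (46, 58, 49 and 40 genes on the left), and with the block genes called higher lie mostly in the upper bins (279 and 270 in the highest pair of bins).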

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

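The tests of general purity, of sequencing depth and of the called human genes against genes of equal level were chosen after the results were seen, as was the requirement that the ribosomal protein genes differ from other short genes beyond the spread of the libraries.

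Across 200 groups of 4 mouse libraries (sequencing totals, list means and named genes), 10 had a library far from the others, and chance gives about 10. In list means, anti-miR-138 replicate 3 had 5.79 log2 CPM of marrow stromal niche factors against 3.34 to 3.69 in the other treated libraries. Anti-miR-138 replicate 1 had 3.39 log2 CPM of B lineage and plasma cell genes against 0.22 to 0.69, and scramble replicate 1 had -1.77 of skeletal muscle genes against -0.22 to 0. Among genes, Bglap stood at 13.52 log2 CPM in scramble replicate 2 against 11.2 to 11.59. Mmp9 stood at 2.47 in anti-miR-138 replicate 4 against 4.32 to 4.62, and Sc5d at 5.34 in anti-miR-138 replicate 6 against 6.64 to 6.8. Wdr78 stood at -1.11 in anti-miR-138 replicate 3 against 2.62 to 3.19. Plau and Dnah7b were detected in 1 scramble library, replicate 3 (-3.29 each), and Klhl6 in 1 treated library, replicate 4 (-2.75), against -3.99 in the libraries with a count of 0.

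Leukocyte genes were lower in OBCs of treated mice although the sort excluded CD45. RNA of leukocytes in the scramble libraries is a candidate explanation: in a second list of 25 leukocyte genes, 0 of them in any of the 32 lists, 23 of 24 tested genes lay below 0 with a median log2 fold change of -1.97 (exact permutation p = 0.0571 for the list means). A lower purity of the scramble sorts in general stays open: the leukocyte and chondrocyte lists moved apart by -4.67 on the log2 scale (exact permutation p = 0.0286), but these were chosen as opposite calls, so that p decides nothing, and the 8 other lists of cell types went both ways, from -0.69 (osteoclast) to 1.4 (megakaryocyte), none beyond the spread of the libraries (exact permutation p = 0.171 to 0.943). The scramble libraries 1 and 3 do not account for the whole difference, since without them it was -3.12. The list means of scramble replicates 2 and 4 (7.11 and 8.5) lay above those of all treated libraries (up to 6.79). Without those libraries the list also passed camera with the preset correlation (adjusted p = 2.21e-12). That call decides little, because with this correlation 20 of the 35 splits of the mouse libraries gave as many lists as the real one. With an estimated correlation and all libraries the camera adjusted p was 0.592. Among abundant leukocyte genes, S100a9 had 644 ± 743 against 6615 ± 7735 CPM and Ptprc 78.2 ± 94.5 against 147 ± 69.6, and an effect of the treatment on leukocytes or on OBCs stays open.

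Ribosomal protein and oxidative phosphorylation genes were lower together in treated mice. A bias against short transcripts could contribute: 474 other genes as short and as abundant had a median log2 fold change of -0.29, and 460 longer genes -0.1 (exact permutation p = 0.0571 for short against longer). Here as short means a longest annotated transcript of 630 to 2677 bases, a range that holds most ribosomal protein genes. Genes were not matched within that range, and the longest annotated transcript need not be the one expressed, so the test is a coarse one. The ribosomal protein genes lay further down, at -0.65, by more than the bound of 0.25 set beforehand but not beyond the spread of the libraries (exact permutation p = 0.314 against the short genes), so this explanation and a treatment effect cannot be told apart. The scramble libraries 1 and 3 are argued against as the whole cause, since without them the lists differed by -0.73 and -0.65. Scramble replicates 2 and 4 lay above all treated libraries in both lists. Both lists also passed camera with the preset correlation without those libraries (the larger adjusted p was 8.63e-06). That call decides little, because with this correlation 20 of the 35 splits of the mouse libraries gave as many lists as the real one. With an estimated correlation and all libraries neither list passed camera (adjusted p = 0.686 and 0.592). With library totals alone the ribosomal protein median lay below that of all genes by -0.59 on the log2 scale, but this test of the scaling decides nothing, because a factor per library moves a list and all other genes alike.

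In the human co-cultures more genes were called lower (207) than higher (27) in the fit without pairs, though not with the pairs as a block (1777 and 1753), and treated libraries detected fewer genes. Sequencing depth is argued against: with every library thinned to the depth of the smallest, the treated library detected fewer genes in 3 of 3 pairs. A background of stray reads in the control libraries could give the slight general trend, since the lowest of 10 equal bins of genes by mean CPM lay below bins 4 to 7 by -0.28 in the median difference between group means of log2 CPM, against at most 0.16 in size in the other treatment assignments within the pairs. For the genes called lower it stays open: all 3413 tested genes of the same mean level had a median of -0.1 (quartiles -0.55 and 0.23) and the called ones -3.09, but these were picked for their fall, so that comparison decides nothing. A treatment effect and a different share of myeloma cell RNA stay open, the latter untested because the identifiers were paired with no names.

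All 35 splits of the mouse libraries gave 0 genes with edgeR's test, the real one included. DESeq2 gave 435 genes for the real split, and 6 other splits drawn at random gave a median of 210, from 139 to 689, with 1 of the 6 as large, so chance is not excluded for DESeq2's genes. For gene lists chance is not excluded either: 20 of the 35 splits gave as many lists as the 6 found, and the highest other split gave 16. At an unadjusted p under 0.05 the real split gave 743 genes and the highest other split 771, with 2 of the 35 splits as large, so chance is not excluded there. For genes with a miR-138 site, 8 of the 35 splits gave a camera p as small, with a -log10 p of 0.37 for the real split and 0.73 for the highest other. The human libraries allow 10 splits, too few for a share under 0.05: the real split, 1 of the 10, gave 234 genes and the highest other 0. With the pairs as a block there are 4 assignments, again too few: the real one, 1 of the 4, gave 3530 genes and the highest other 0.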

How the results depend on the processing

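The fits without the scramble libraries 1 and 3 and the permutation of list means were chosen after the results were seen. For mouse genes, edgeR's count of 0 held with RLE scaling, library totals alone, limma-voom weights, the CPM filter, the title number as a replicate block and any 1 library left out, while DESeq2 gave 435 and the fit with no filter 10. The scaling moved the median log2 fold change of all mouse genes from -0.1 (TMM) to 0.11 (library totals alone). The mouse title numbers, 3 of them in both groups, were not taken as pairs, since same-numbered libraries correlated at 0.01, 0.07 and 0.1. For human genes, RLE scaling gave 231, library totals alone 276 and limma-voom weights 285, against 234. DESeq2 gave 878, no filter 505, the CPM filter 131, the replicate block 3530, and 1 library left out 0 to 1; fewer libraries or a different set of tested genes enter some of these, and the cause was not tested otherwise. Of the mouse lists, 5 to 11 passed camera with 1 library left out against 6 (11 without scramble replicate 1 and 10 without scramble replicate 4), 13 without the scramble libraries 1 and 3, and 0 with an estimated correlation or by permutation of list means. The permutation, with a smallest p of 0.0286 and 32 lists, could pass after adjustment only with many lists at that p, so its 0 decides little. Genes with a site kept a p by camera of 0.284 to 0.703 with 1 library left out. Without the scramble libraries 1 and 3, the bone matrix (adjusted p = 0.0129) and immediate early (0.00298) lists turned to higher and the mitochondrially encoded list no longer differed (0.904), whereas without scramble replicate 4 the bone matrix (0.0262) and immediate early (0.0204) lists passed in the lower direction. Without the scramble libraries 1 and 3 the log2 fold changes of Alpl (0.05), Spp1 (0.36) and Dmp1 (0.21) turned positive. The log2 fold changes of Spp1 with limma-voom weights (0.12), Sp7 with the replicate block (0.08), the Pecam1 log2 fold change (-2.29 to 1.46 with 1 library left out, positive without scramble replicate 4) and Rock2 (-0.61 to 0.28, negative without anti-miR-138 replicate 4) also turned. A change of sign was counted only where a value lay over 1 SE from 0 or had passed. The mouse spread limits what can be seen: in simulated data 0 of 50 genes changed 4-fold were recovered. Human gene lists, human miR-138 sites and the comparisons of mouse with human genes were not run.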
